A study of Mus musculus with 2 samples.

How the data were processed

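The material was liver from B6NCrl mouse embryos of day 13.5, male and female embryos pooled. At this stage the fetal liver is the main site of blood formation and also holds immature hepatocytes. Histone H3 trimethylated at lysine 9 (H3K9me3), a mark of heterochromatin, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq), in which DNA bound to the modified histone is recovered with an antibody and sequenced. The labels give 2 biological replicates of 1 group and no second condition, so no comparison between conditions was made. The library fragments were selected at 300 to 500 bp, per the labels.

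The authors deposited 4 peak lists on the mm10 (GRCm38) assembly. Per the file headers and the descriptions deposited with the files, 1 list was called on replicate 1, 1 on replicate 2 and 1 on both replicates pooled, each against a control alignment, and the replicated list was derived from these 3. The replicates had different control files and the pooled list used both. The aligner, the peak caller, their versions and the calling thresholds are not given in the sources used here. Every line of the replicated list was found to be a line of the pooled list. Each peak carries a signal value, which is the enrichment that the authors' caller gave it, and a −log10 p and −log10 q, as deposited. These values are the authors', and were used only to describe, rank or filter peaks within their own list. The lowest deposited −log10 p was 2.01 in replicate 1 and 2.02 in replicate 2, so weaker enrichment was not analysed here. Read counts were not used here, the sequencing depth of each replicate is unknown, and no interval that needs the depth was computed.

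The tests asked where peaks lay, and their p-values compare observed positions with shuffled positions in these 2 samples. They do not measure the spread between samples. A peak list was rotated by a random offset along each chromosome, between its first and last known base, which kept the spacing of the peaks. The share of interest was computed for 1000 rotations, or for 10000 for gene lists. The two-sided p was the smaller tail doubled, and its smallest possible values were 0.0020 and 0.00020. Benjamini-Hochberg adjustment was made over the 4 annotation classes or the 18 gene lists, with a threshold of 0.05. The replicated list was the main list, and each replicate list was tested beside it.

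The genes were those of GENCODE release M21 on the 21 assembled chromosomes, which include 21938 protein-coding genes. Peaks on unplaced scaffolds entered no test. A gene was occupied if its body overlapped a peak by at least 1 bp. The start window covered 1 kb either side of the annotated start. Peak summits were assigned, in this order, to a start window of any transcript, an exon, an intron or intergenic sequence. Chromosome density was covered bp per known base, relative to the 19 autosomes. Clusters were bins of 1 Mb ranked by covered bp. The genome sequence was RefSeq's GRCm38.p6, and it also gave the GC content, the share of soft-masked bases (the masking method is not given in the sources used here) and, for 32-mers taken every 16 bp, the share found once in the genome.

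The 18 gene lists, the tests and the rule for named genes were fixed before the data were examined. The lists were the zinc finger genes, the olfactory receptors, the vomeronasal receptors, the clustered protocadherins, the Hox genes, the ribosomal proteins, the replication-dependent histones, imprinted genes, hepatocyte genes on in fetal liver, hepatocyte genes of the adult liver, erythroid genes, other cell types of the fetal liver, neuronal genes, muscle genes, germline genes, 2-cell stage genes, factors of H3K9 methylation and heterochromatin, and the cytochrome P450 family. Of the 46 imprinted symbols, 38 were protein-coding and entered the test. The rule named up to 4 members per list with the largest covered share among members overlapped in both replicate lists, the 20 coding genes with the most covered bp, the genes at the 10 peaks with the highest signal value in start windows, up to 5 genes in each of the 5 bins with the most covered bp, and every imprinted gene with a replicated peak. Further members of lists with few occupied genes, and the germline genes with a peak at their start, were named after their values were seen.

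Alternatives tried were a −log10 q of at least 2, each replicate list alone, other overlap rules, lists of equal length, independent placement of peaks, a start window of 2.5 kb, occupancy of the start window, at least 10% of the body covered, 10000 random gene lists matched on length, and bins of 500 kb. Alternatives added after seeing the data were the window 1 kb either side of the gene end, the peaks whose 32-mers all occur once, and the replicated peaks that overlap both replicate lists. The gene list test was tested on simulated data. Over 100 rotated peak lists, 2.06% of tests on the 18 unchanged lists had an unadjusted p below the threshold and 0% of the data sets had a list past the adjusted one. Both these lists and their reference were rotations, so a low rate was fixed in advance. It cannot show that rotation is a fair comparison for the real peaks. With peaks planted in 10%, 20% and 40% of the members of a list, an unadjusted p below the threshold was reached in 50.0%, 84.4% and 100% of 90 tests. Overlap counts equalled those of bedtools 2.31.1. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.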

Results

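H3K9me3 was mapped in 2 biological replicates of day 13.5 mouse fetal liver, each with its own peak list, and with lists called on the pooled reads. The replicate 1 list held 51686 peaks over 13.2 Mb and the replicate 2 list 95387 peaks over 25.4 Mb. The pooled list held 84927 peaks over 24.6 Mb, and the replicated list, a part of the pooled one, held 17640 peaks over 8.22 Mb. The replicated peaks on assembled chromosomes covered 0.304% of known bases. They had a median length of 386 bp, the longest was 8946 bp, and 722 were longer than 1 kb. A −log10 q of at least 2 was reached by 36.7% of pooled peaks and by 80.6% of the replicated peaks among them. In the separately called lists it was reached by 11.6% of replicate 1 peaks and 10.7% of replicate 2 peaks, and these values are not comparable with those of the pooled call. Depth is unknown, so the difference in list length between the replicates cannot be set against it.

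The replicates marked shared places far more often than rotated lists did, and most often at their strongest peaks. Of the replicate 1 peaks, 28.4% were overlapped by a replicate 2 peak, against 2.08% (middle 95%, 1.81% to 2.58%) for rotated lists, which was 13.7-fold. In the other direction 15.2% of replicate 2 peaks were overlapped, against 1.13% (0.982% to 1.40%), which was 13.5-fold. Both two-sided permutation p-values were 0.0020, the smallest that 1000 rotations can give. Of the 100 peaks with the highest −log10 p, 100 in replicate 1 and 99 in replicate 2 were overlapped by the other list, and of the 1000 highest, 79.8% and 79.2% were. The overlap was 53.1% in the highest rank decile of replicate 1 and 21.5% in the lowest, and 36.7% and 8.72% in replicate 2. Rotated shares were computed over all peaks and not per decile. Longer peaks are easier to overlap, and length was not matched across deciles, so the trend with rank was not tested. Of the replicated peaks, 79.2% overlapped both replicate lists, 7.38% replicate 1 alone, 13% replicate 2 alone and 0.465% neither.

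**Figure D1:**
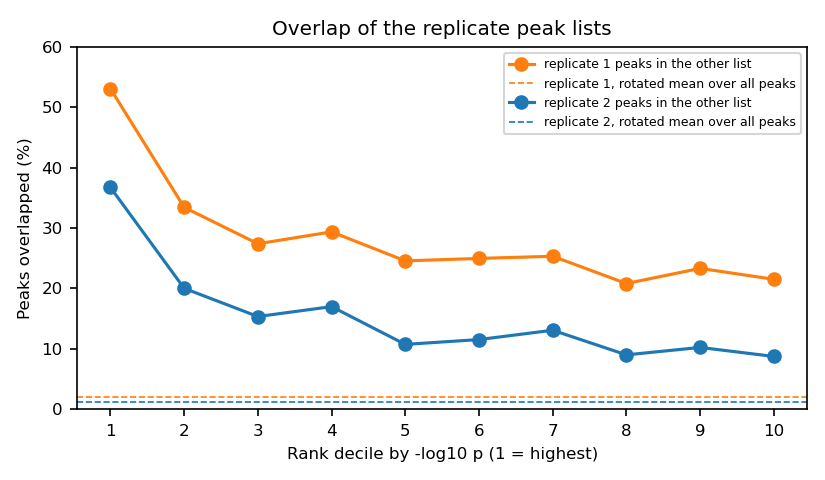
Share of the peaks of each replicate list (y axis, percent) overlapped by the other list, in 10 rank deciles by −log10 p (x axis, 1 is the highest). Points are observed shares and dashed lines the rotated means over all peaks, 2.08% for replicate 1 and 1.13% for replicate 2, and every decile lies above its dashed line.

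Peaks were unevenly spread over chromosomes. Chromosome 5 carried 2360 replicated peaks and 2.37 times the covered share of the autosomes as a whole. Chromosome 4 (1.51), chromosome 7 (1.38) and chromosome 17 (1.33) were also above 1, and chromosome 14 had the lowest autosomal ratio of the replicated list, 0.491. Chromosome X carried 128 peaks at a ratio of 0.143 and chromosome Y 15 peaks at 0.0304. The replicate lists gave 1.77 and 1.65 for chromosome 5, 1.19 and 1.13 for chromosome 4, 0.701 and 0.737 for chromosome 14, 0.120 and 0.266 for chromosome X, and 0.0244 and 0.0118 for chromosome Y. In both replicate lists chromosomes 7, 8 and 17 were above chromosome 4, and in replicate 2 the lowest autosome was chromosome 11 (0.662). Of the 128 peaks on chromosome X, 35 lay from 169 Mb onwards, a stretch that holds the pseudoautosomal gene Asmt, and these made up 37.8% of the covered bp of the chromosome. Without them the ratio was 0.0889. Unique 32-mers made up 69.2% of random windows on chromosome X and 84.5% on autosomes. On chromosome Y they made up 3.29%. Chromosomes are not replicates, and no test was made.

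**Figure D2:**
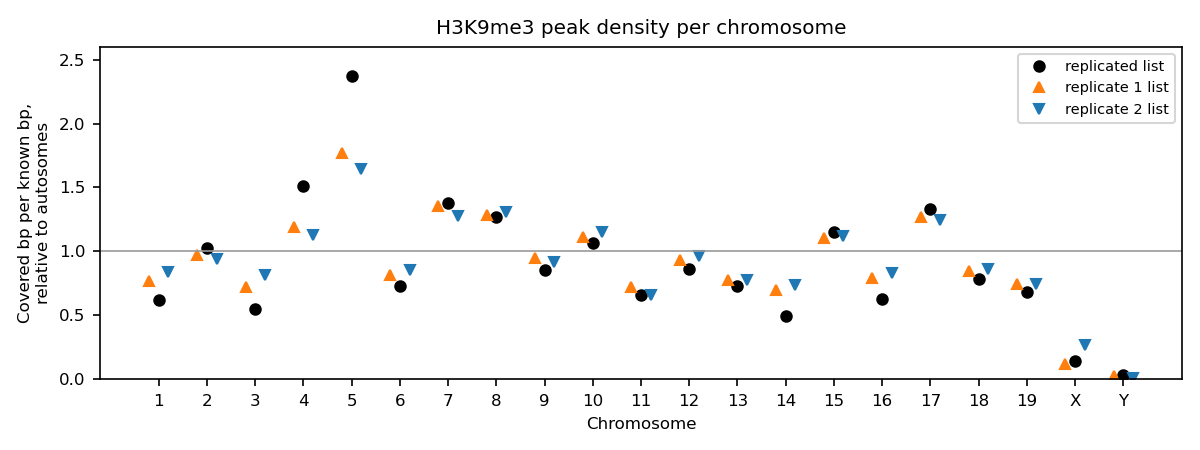
Covered bp per known base on each chromosome relative to the autosomes as a whole (y axis), by chromosome (x axis), for the replicated list (circles) and the replicate 1 and replicate 2 lists (triangles). The line marks a ratio of 1; chromosome 5 is the highest in all 3 lists, at 2.37, 1.77 and 1.65, and chromosomes X and Y are the lowest.

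The bins of 1 Mb with the most covered bp lay on chromosomes 4 and 5. The first, on chromosome 5 from 127000001 to 128000000, held 222 replicated peaks over 125 kb, and its peaks overlapped Tmem132d, Tmem132c and Glt1d1. Chromosome 4 from 153000001 to 154000000 held 193 peaks over 112 kb, with Ajap1 as its only overlapped coding gene. Chromosome 5 from 116000001 to 117000000 held 193 peaks over 107 kb and overlapped Srrm4, Cit and Ccdc60. Chromosome 4 from 152000001 to 153000000 held 160 peaks over 106 kb and overlapped Nphp4, and chromosome 5 from 125000001 to 126000000 held 178 peaks over 99.1 kb and overlapped Tmem132b, Scarb1 and Ncor2. The top 1% of bins held 20.8% of all covered bp in the replicated list, but 12.7% in the replicate 1 list and 10.9% in the replicate 2 list. Of the 5 bins, 4 were among the 5 highest of the replicate 1 list and 2 among those of the replicate 2 list.

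The coding gene with the most covered bp was Tmem132d, which encodes a membrane protein. Tmem132d (chromosome 5, 127781630 to 128433077) had 209 replicated peaks over 115 kb, 17.6% of its body, with 97.9 kb covered in replicate 1 and 158 kb in replicate 2. Cdh13, which encodes T-cadherin (chromosome 8, 118283733 to 119324921), had 193 peaks over 93.5 kb, 8.98% of its body, and Tmem132b had 84 peaks over 50.1 kb. Csmd2 (35.7 kb), Sdk1 (31.5 kb), Galnt17 (29.99 kb), Mtus2 (28.5 kb), Caln1 (27.02 kb), Cdh4 (25.6 kb), Tmem132c (24.1 kb), Ptprt (21.7 kb), Alk (18.8 kb), Ajap1 (17.1 kb) and Dok5 (15.3 kb) were among the 20 as well. So was Ttn, which encodes the muscle protein titin, at 26.7 kb. Most of these genes had their strongest peak in an intron. Mroh2a (chromosome 1, 88226986 to 88262289) stood apart, since 82.0% of its 35.3 kb was covered in the replicated list, 70.02% in replicate 1 and 72.6% in replicate 2. Its strongest peak lay in a coding exon, as did that of Ttn. The models Gm42416, Gm37013 and Gm37388 span the clustered protocadherins and Gm20388 spans 4435 kb of chromosome 8, so their covered bp belong to other genes too.

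Replicated peak summits lay outside genes more often than rotated ones. Intergenic sequence held 58.2% of summits against 49.9% (middle 95%, 46.7% to 53.5%), and introns 30.8% against 40.2% (37.2% to 42.9%), both with a permutation adjusted p of 0.0027, and both replicate lists showed these directions past the threshold. Exons held 4.60% against 3.43% (adjusted p 0.0027), made up of 418 summits in coding sequence, 175 in untranslated regions and 207 in exons of non-coding transcripts. The exon result was not shared by the replicate lists, which gave 3.388% against 3.401% (adjusted p 0.951) in replicate 1 and a lower share, 2.95% against 3.36% (adjusted p 0.0020), in replicate 2. Start windows held 6.41% of summits in the replicated and in the rotated lists (adjusted p 0.965), but fewer than rotated in replicate 1 (5.27% against 6.35%, adjusted p 0.0027) and replicate 2 (4.89% against 6.28%, adjusted p 0.0020). Replicated peaks had a GC content of 48.4%, against 42.2% for 1 rotation of the list, and 25.3% of their bases were soft-masked, against 33.8%.

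Of the 21938 protein-coding genes, 2131 (9.71%) overlapped a replicated peak. Among the 18 gene lists, the zinc finger genes, the clustered protocadherins and the imprinted genes were occupied more often than under rotated peaks, and each of the 3 also passed in both replicate lists, at smaller folds over rotation. The other 15 lists did not pass on gene bodies in the replicated list.

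Zinc finger genes, which encode a large family of DNA-binding proteins, were occupied at 115 of 395 members, 29.1% against 11.7% under rotation (7.85% to 16.2%, permutation adjusted p 0.0012). The replicate lists gave 39.2% against 26.96% (adjusted p 0.0012) and 48.1% against 38.2% (adjusted p 0.032). Zfp646 (chromosome 7, 127876221 to 127885996) was covered over 50.6% of its body, with its strongest peak in a coding exon. Zfp146 was covered over 49.1%, also with a coding exon at its strongest peak, while in Zfp873 (40.8%) and Zfp110 (37.1%) that peak lay in an untranslated exon. The peaks sat toward the ends of the genes. Start windows were occupied in 5 members (Zfp988, Zfp541, Zfp575, Zfp872 and Zfp445), 1.27% against 1.79% (adjusted p 1). In replicate 1 they were occupied less often than under rotation (1.52% against 4.56%, adjusted p 0.017), and in replicate 2 they did not pass (4.05% against 7.84%, adjusted p 0.062). Over all coding genes start windows were occupied at 2.32% in replicate 1 and 3.70% in replicate 2. The window 1 kb either side of the gene end, added after seeing the data, was occupied in 46 members, 11.6% against 1.78% (adjusted p 0.0036), and the replicate lists gave 15.19% against 4.53% and 17.97% against 7.86% (adjusted p 0.0036 each). That was 6.54-fold in the replicated list, 3.36-fold in replicate 1 and 2.29-fold in replicate 2. Mean coverage was 0.150% in the first twentieth of the body and 7.30% in the twentieth before the last.

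**Figure D3:**
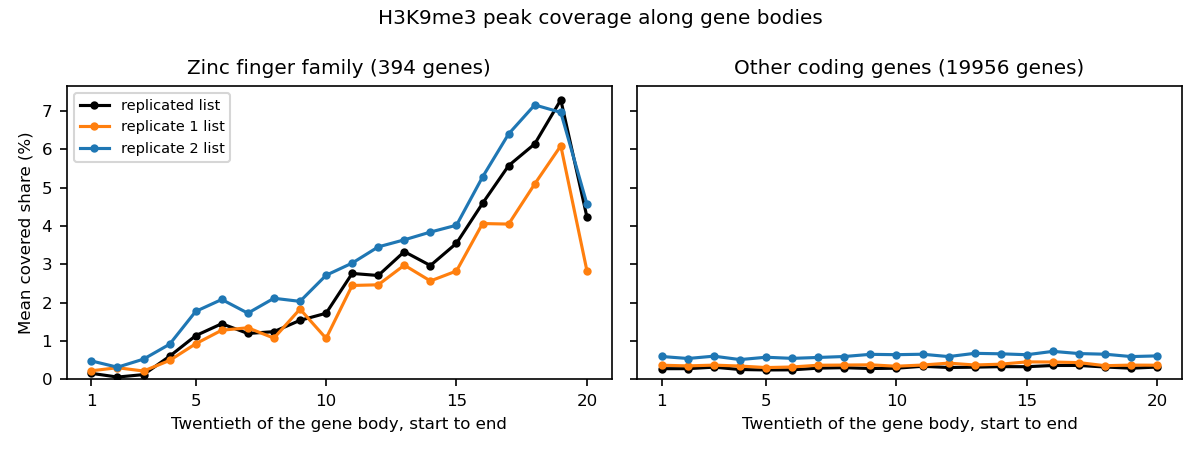
Mean share of the gene body covered by peaks (y axis, percent) in 20 equal parts from start to end (x axis), for 394 zinc finger genes and 19956 other coding genes of at least 2 kb, with 1 line per peak list. In the replicated list the zinc finger genes go from 0.150% in part 1 to 7.30% in part 19, and the other genes lie between 0.239% and 0.356%.

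The clustered protocadherins, cell surface proteins that neurons choose in combinations, were occupied at 49 of 57 members, 86.0% against 22.2% under rotation (0% to 61.4%, permutation adjusted p 0.0012). Bodies in the replicate lists were occupied at 92.98% against 44.1% (adjusted p 0.0012) and 96.5% against 55.3% (adjusted p 0.0036). Many alpha and gamma members share the end of their bodies, so 1 peak can occupy several of them. Start windows, which are separate, were occupied in 25 members, 43.9% against 1.29% (0% to 7.02%, adjusted p 0.0024). The replicate lists gave 47.4% against 3.73% (adjusted p 0.0036) and 61.4% against 6.75% (adjusted p 0.0024), which was 12.7-fold and 9.10-fold, smaller than the 34.1-fold of the replicated list. Among members overlapped in both replicate lists the largest covered shares were in the beta cluster, with Pcdhb12 at 51.1%, Pcdhb3 at 42.1%, Pcdhb13 at 36.1% and Pcdhb4 at 34.9%, each with its strongest peak in a coding exon. The strongest peaks of Pcdhb12 and Pcdhb4 had 67.6% and 74.5% unique 32-mers, so part of each peak has further copies in the genome.

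**Figure D4:**
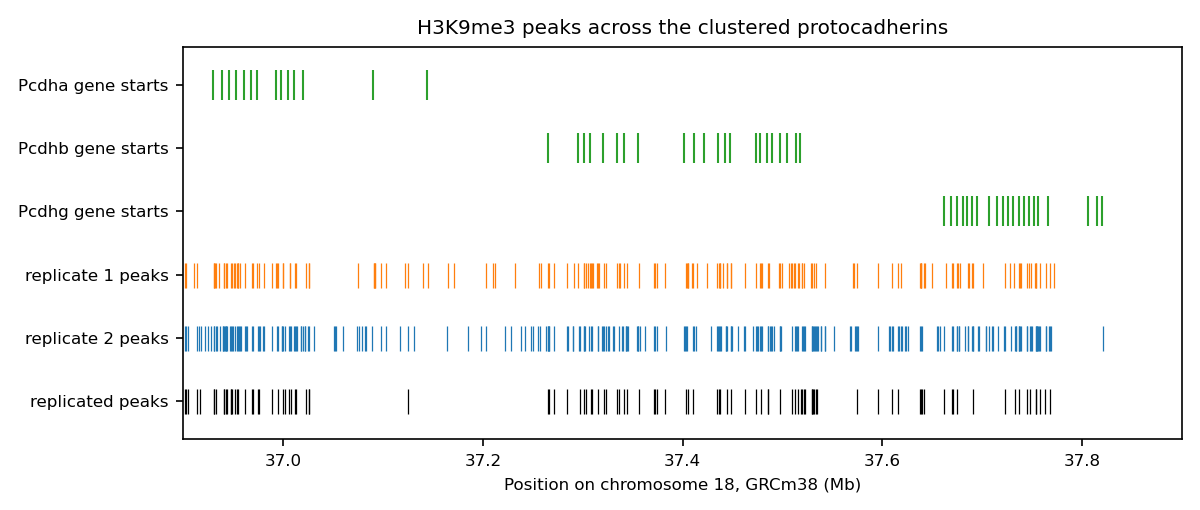
Clustered protocadherins on chromosome 18 from 36.9 to 37.9 Mb (x axis, GRCm38), with a tick at each annotated gene start of the alpha, beta and gamma clusters and a tick at the midpoint of each peak. The stretch holds 171 replicate 1 peaks, 267 replicate 2 peaks and 106 replicated peaks, and 25 of the 57 start windows hold a replicated peak.

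Imprinted genes, which are expressed from the copy of a single parent, were occupied at 21 of 38 coding members, 55.3% against 20.5% under rotation (7.89% to 34.2%, permutation adjusted p 0.0012). The replicate lists gave 68.4% against 39.8% (adjusted p 0.0012) and 71.1% against 49.985% (adjusted p 0.032). Start windows were occupied in 10 members, 26.3% against 1.76% (adjusted p 0.0018), namely Nnat, Gnas, Sgce, Peg10, Peg3, Usp29, Magel2, Cdkn1c, Zrsr1 and Slc38a4. In each replicate list 34.2% of the start windows were occupied, against 4.58% in replicate 1 (adjusted p 0.0036) and 7.85% in replicate 2 (adjusted p 0.0018). The excess over rotation was thus 7.47-fold and 4.36-fold, smaller than the 14.9-fold of the replicated list. Cdkn1c, an inhibitor of the cell cycle (chromosome 7, 143458339 to 143461050), was covered over 83.0% of its body in the replicated list, 61.1% in replicate 1 and 84.2% in replicate 2. The peak at the start shared by Peg10 and Sgce lay at 4747402 to 4747947 of chromosome 6, and that shared by Peg3 and Usp29 at 6729094 to 6730604 of chromosome 7. The peak at the Gnas start (chromosome 2, 174284299 to 174287253) also covered part of the antisense transcript Nespas. Zrsr1, inside Commd1, was covered over 21.4%, and Nnat, inside Blcap, over 20.8%.

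Other imprinted genes carried replicated peaks away from their annotated starts. Only the outermost start of a gene was used, so such a peak may lie at the start of another of its transcripts. Kcnq1 had 11 peaks over 6.22 kb, which all lay within the antisense transcript Kcnq1ot1, whose own start window was marked. Igf2r had a single peak at 12741977 to 12742896 of chromosome 17, in an intron and overlapping the start window of the antisense transcript Airn. The start window of Igf2r itself was marked in each replicate list but not in the replicated list. Mest (2.30 kb covered), Impact (2.36 kb), Grb10 (1.72 kb), Blcap (1.23 kb), Trappc9 (1.10 kb), Commd1 (0.961 kb), Plagl1 (0.885 kb), Zdbf2 (0.586 kb), Rasgrf1 (0.379 kb) and Inpp5f (0.362 kb) had peaks in their bodies. Some of these peaks lie at starts of genes within them. The Commd1 peak is that at the Zrsr1 start, the strongest Trappc9 peak is that at the Peg13 start, and Blcap includes the Nnat peak. Among the non-coding imprinted transcripts, start windows of H19, Meg3, Mirg and Peg13 were marked too, those of H19 and Mirg in replicate 2 but not in replicate 1. The Mirg peak, at 109730749 to 109731140 of chromosome 12, reached only the edge of the window. The peak near the H19 start had a −log10 q of 1.57 and the only Zdbf2 peak of 1.24, both below 2.

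Germline genes did not pass on gene bodies but did at their starts. Bodies were occupied in 13 of 42 members, 31.0% against 14.6% (permutation adjusted p 0.056). Replicate 1 alone gave 33.3% against 34.5% (0.967-fold, adjusted p 1) and replicate 2 alone 52.4% against 47.9% (1.09-fold, adjusted p 0.718), below the 2.12-fold of the replicated list. Start windows were occupied in 8 members, 19.05% against 1.49% (0% to 7.14%, adjusted p 0.0018). The replicate lists gave 16.7% against 3.94% (adjusted p 0.017) and 35.7% against 7.11% (adjusted p 0.0018), which was 4.23-fold and 5.02-fold, smaller than the 12.7-fold of the replicated list. The 8 were Ddx4 and Dazl, which encode RNA-binding proteins of germ cells, Sycp1, Sycp2, Stag3 and Dmc1, which act in meiosis, Taf7l and Rpl10l. Rpl10l also counts among the 2 occupied ribosomal protein genes. The Dazl peak (chromosome 17, 50293095 to 50294163) had a signal value of 7.59 and the Ddx4 peak (chromosome 13, 112651610 to 112652809) of 6.21. Taf7l was marked at its start in replicate 2 and not in replicate 1. Meioc and Piwil1 had peaks in their bodies, with 6.92% and 4.46% covered.

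**Figure D5:**
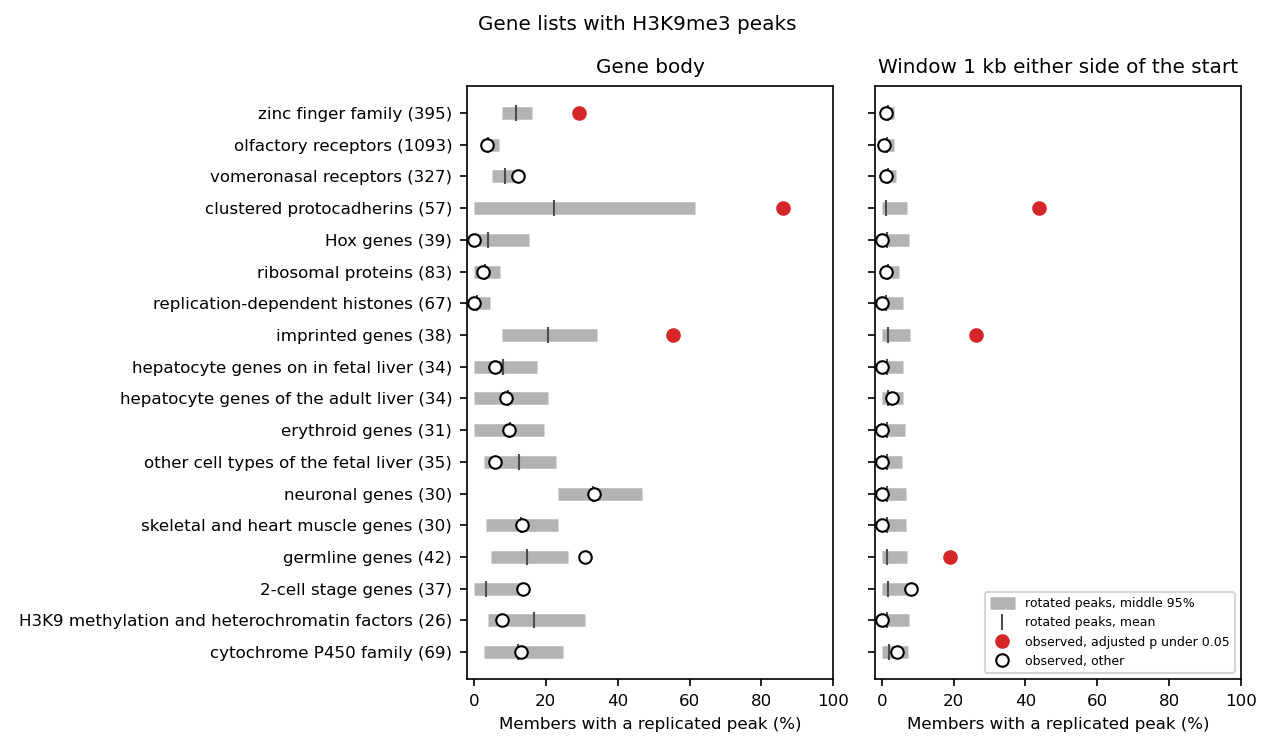
Share of the members of each gene list with a replicated peak (x axis, percent) in the gene body (left) and in the window 1 kb either side of the start (right), with the number of members in parentheses. Grey bars are the middle 95% of 10000 rotations and ticks their means; filled points passed an adjusted p of 0.05, which were 3 lists on each side.

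The genes that the fetal liver uses were not occupied beyond rotation, and neither were neuronal or muscle genes. Hepatocyte genes on in fetal liver were occupied in 2 of 34 members (5.88% against 8.02%, permutation adjusted p 1), which were Ambp and Serpina1b, with 5.91% and 0.349% of their bodies covered. Hepatocyte genes of the adult liver were occupied in 3 of 34 (8.82% against 9.52%) by body overlap, namely Ass1, Cyp3a11 and Cyp2c29. Erythroid genes were occupied in 3 of 31 (9.68% against 10.2%), namely Ank1, Sptb and Zfpm1, of which Zfpm1 had 5.19% of its body covered. Other cell types of the fetal liver had 2 of 35 members occupied, Adgre1 of macrophages and Pdgfrb of stromal cells, 5.71% against 12.5% (adjusted p 0.712). That list passed as lower in both replicate lists, at 11.4% against 28.5% (adjusted p 0.048) and 14.3% against 38.9% (adjusted p 0.013). Over all coding genes the share was 19.5% and 26.6%, and introns as a class also fell below rotation in both replicate lists. Against random gene lists of matched length that list did not pass (5.71% against 8.71%, adjusted p 0.978). That check used the replicated peaks, where the list did not pass under rotation either, so it does not bear on the replicate results. The shares over all coding genes and introns leave open whether the low share is particular to that list, which was not tested further. Neuronal genes had 10 of 30 occupied, 33.3% against 33.2%, among them Slc17a7 with 22.6% of its body covered, Grin2b, Syt1 and Dlgap1. Muscle genes had 4 of 30 occupied, 13.3% against 13.1%, which were Ttn, Ckm, Ryr1 and Myh8. The permutation adjusted p was 1 for the hepatocyte, erythroid, neuronal and muscle lists.

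Of the remaining lists, none passed with the replicated peaks. No Hox gene of 39 and no replication-dependent histone gene of 67 overlapped a replicated peak, against 4.03% and 0.914% under rotation. Ribosomal protein genes were occupied in 2 of 83 (Rpl3 and Rpl10l), olfactory receptors in 38 of 1093 (3.48% against 3.95%) and cytochrome P450 genes in 9 of 69 (13% against 12.2%), for all of which the permutation adjusted p was 1. Olfr398 (18.7%), Olfr769 (18.2%), Olfr1349 (15.2%) and Olfr1350 (12.2%) had the largest covered shares among the olfactory receptors overlapped in both replicate lists, and Cyp3a11 (5.58%), Cyp3a16 (5.51%), Cyp2b19 (4.60%) and Cyp3a57 (1.58%) among the cytochrome P450 genes. Vomeronasal receptors were occupied in 40 of 327 (12.2% against 8.76%, adjusted p 0.429), led by Vmn1r43 (19.5%), Vmn1r70 (13.8%), Vmn1r42 (10.1%) and Vmn1r46 (5.95%), of which Vmn1r42 and Vmn1r43 overlap and share peaks. Genes of the 2-cell stage were occupied in 5 of 37 (13.5% against 3.43%, adjusted p 0.184), with Duxf3 at 21.7% and Pramel7 at 8.60% of the body, besides Pramel1, Usp17lb and Usp17le. In the replicate lists it was 21.6% against 8.93% (adjusted p 0.188) and 16.2% against 14.8% (adjusted p 0.926). With peaks whose 32-mers all occur once 0 of 37 were occupied, against 2.03% under rotation. So few were expected there that this 0 cannot show a loss. The strongest Duxf3 peak had 60% unique 32-mers. Factors of H3K9 methylation and heterochromatin were occupied in 2 of 26, Setdb1 and Atf7ip (7.69% against 16.8%, adjusted p 0.712). They were lower than rotated in replicate 1 (11.5% against 38.9%, adjusted p 0.017) and did not pass in replicate 2 (42.3% against 53.4%, adjusted p 0.492), and the difference between the replicates was not tested. The only replicated peak of Setdb1 had a −log10 q of 1.24, below 2.

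The strongest peaks overlapping start windows of coding genes were at Trim56, Gm21887, Dazl, Cdkn1c, Muc3, Tcfl5, Ddx4, Gnas and Asmt. Trim56, a ubiquitin ligase of innate immunity (chromosome 5, 137105644 to 137116209), held the highest, with a signal value of 9.31 and a −log10 q of 31.7. That peak, at 137112482 to 137115339, had its summit in a coding exon of the gene body and reached only the edge of the start window. The body of Trim56 was covered over 51.8%, and its start window was marked in replicate 2 and not in replicate 1. The Muc3 peak (signal value 6.45) lay upstream of the gene, at 137149522 to 137151919 of the same chromosome. Tcfl5 had a signal value of 6.38. Asmt, which encodes the last enzyme of melatonin synthesis (chromosome X, 170672644 to 170678054), was covered over 96.95% of its body, and a peak in it had a signal value of 15.2, the highest of the replicated list. Gm21887, also on chromosome X, had a signal value of 8.79, but none of the 32-mers of that peak was unique and their median number of copies was 2.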

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

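Unplaced scaffolds entered no comparison, and 235 replicated peaks lay on 20 of them. That was 44.8 peaks per Mb, 6.22 times the autosomal density, but the ratio was 2.69 in replicate 1, 1.63 in replicate 2 and 1.74 in the pooled list, and no test of an excess was made.

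Among the tests below, those of unique sequence on chromosome X, of scaled signal values, of peak length and of peaks whose 32-mers all occur once were chosen after results had been seen.

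Chromosome X carried few peaks, at 0.143 times the autosomal density. Neither less unique sequence nor lower GC content accounted for this alone, since the ratio was 0.175 per unique bp (0.146 and 0.325 in the replicate lists) and 0.212 in 1 kb bins of equal GC content (0.154 and 0.329). Fewer copies of the chromosome in a mixed-sex pool stay open: among peaks with a signal value in the top 10% of autosomal ones the ratio was 0.188 (95% Poisson interval 0.121 to 0.277; 0.141 and 0.184 in the replicate lists), and 13 of these 25 peaks on chromosome X lay from 169 Mb onwards, without which it was 0.0900. The interval takes the peaks as independent although they lie in clusters, so it is too narrow. The expectation set in advance for this cause, that strong peaks would be spared, was not met. Autosomal signal values scaled to 0.75, the copies in equal numbers of both sexes, would give a ratio of 0.0717 at that fixed minimum. But a signal value is an enrichment against a control, in which the copies may be fewer too. Such scaling may thus not describe fewer copies, and neither value decides the question. The controls and the caller's own filters stay open too, and no biological explanation was tested.

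Zinc finger genes and protocadherin starts belong to families of similar sequence. With the peaks whose 32-mers all occur once, zinc finger bodies were still occupied 2.46 times as often as under rotation. Fewer members were occupied, 74 of 395, and both shares were lower (18.7% against 7.61%). Protocadherin starts were occupied 37.0 times as often (16 of 57), with a permutation p of 0.00020 for each, the smallest possible. The filter asks for exact copies, so copies that differ by a few bases can pass it. Random gene lists matched on length and GC content of the gene body averaged 7.27% for zinc finger bodies, against 29.1% observed. For protocadherin starts they averaged 1.33%, against 43.9%. Their middle 95% reached up to 9.62% and 5.26%. These ranges are too narrow, since the lists take genes as independent while genes of a family lie in clusters. For zinc finger bodies the mean share given by length and GC content was thus below the observed one. GC content at the starts was not matched, so for protocadherin starts it stays open. Antibody specificity and the controls stay open, and no biological explanation was tested.

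The strongest peaks lay more often in sequence with further copies. Of the 100 replicated peaks with the highest signal value, 72.0% held a 32-mer found elsewhere, against 39.2% of the others (two-sided Fisher exact p 4.3e-11). Their median length was 1078 bp against 384 bp, but among other peaks of matched length the mean was 54.2% (middle 95%, 45.0% to 63.0%), so length left part of the excess. Reads of several copies placed on 1 copy may therefore add to some of these values. Mostly repeated sequence, with fewer than 50% unique 32-mers, was also more frequent, in 9 of the 100 against 0.896% of the others. No biological explanation was tested.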

How the results depend on the processing

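The end window, the peaks whose 32-mers all occur once and the peaks that overlap both replicate lists were chosen after results had been seen. Of 313 alternative values for 56 results, 230 were taken as unchanged, counting 32 that changed direction with neither value past the threshold. The others of these kept their direction and side of the threshold or moved by less than the spread between replicates. For counts and covered lengths the rule was looser, since they were taken as unchanged within 1.5-fold. The overlap of the replicate lists stayed at the smallest possible permutation p under every alternative run, between 13.4-fold and 75.1-fold. Zinc finger, protocadherin and imprinted gene bodies stayed past the threshold with each replicate list, with 10% of the body covered, against random gene lists, at a −log10 q of at least 2, with peaks whose 32-mers all occur once and with peaks that overlap both replicate lists. Their folds fell by over 1.5 times with the replicate 1 and the replicate 2 list, for zinc finger genes from 2.49 to 1.46 and 1.26, for protocadherins from 3.87 to 2.11 and 1.74, and for imprinted genes from 2.70 to 1.72 and 1.42. The replicate lists are longer, so their rotated shares are higher, which limits the fold that can be reached. For protocadherins the rotated share was 22.2% in the replicated list and 55.3% in replicate 2, where 96.5% were occupied. A smaller fold there need not mean a weaker excess.

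At a −log10 q of at least 2 the lists held 5988 (replicate 1), 10218 (replicate 2) and 31143 (pooled) peaks. The lists past the threshold numbered 6 against random gene lists, 1 with the end window, and between 4 and 5 with a single replicate list. Against random gene lists of matched length germline genes passed at 2.87-fold, vomeronasal receptors at 2.34-fold and 2-cell stage genes at 4.72-fold. The last 2 passed under no other alternative, and 2-cell stage genes were at 1.10-fold with the replicate 2 list. With peaks whose 32-mers all occur once, 2-cell stage genes were at 0-fold. Rotation gave only 2.03% there, so that 0 cannot show a loss. With start windows germline genes passed at 12.7-fold and zinc finger genes turned to 0.708-fold. With end windows protocadherins (9.38-fold) and imprinted genes (1.52-fold) no longer passed.

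With a single replicate list the density ratio lay between 1.65 and 1.77 for chromosome 5, 0.120 and 0.266 for chromosome X, and 0.0118 and 0.0244 for chromosome Y, and for chromosome 2 it turned from 1.02 to between 0.938 and 0.974. The ratio for chromosome 5 was 2.21 by peaks per Mb. The share of summits relative to rotated ones turned to between 0.780 and 0.831 for start windows and between 0.878 and 0.996 for exons. Germline bodies stayed short of the threshold at 1.09-fold and 0.967-fold. Other cell types of the fetal liver passed as lower (0.367-fold and 0.401-fold), and heterochromatin factors passed as lower in replicate 1 (0.297-fold). Against random gene lists of matched length, with the replicated peaks, they were at 0.656-fold and 0.640-fold, and neither passed. With those peaks neither list passed under rotation either, so this does not bear on the replicate results. The top 1% of bins held between 10.9% and 12.7% of covered bp, and 25.1% with bins of 500 kb. The cause was not tested for any of these changes. Depth is unknown, so what it limits could not be computed. No paired analysis was possible because there was a single group.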

Other observations

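Gene families outside the fixed lists were scanned after the main results were seen, by the stem of the gene symbol, for 240 stems with at least 10 coding genes. Only 1 family, the secretoglobins, passed in the replicated list and had an unadjusted p below the threshold in each replicate list. Secretoglobins are small secreted proteins, some of which bind androgens. Of 34 members, 8 were occupied, 23.5% against 2.24% under rotation (permutation adjusted p 0.014, 100000 rotations), with p 0.0020 and 0.0030 in the replicate lists. The 8 were Scgb2b2, Scgb1b2, Scgb2b3, Scgb2b21, Scgb2b24, Scgb2b26, Scgb2b27 and Scgb1b30, between 31290508 and 34100837 of chromosome 7. Their start windows did not pass (adjusted p 0.053). A first run of 2000 rotations gave the family a permutation adjusted p of 0.240 and could not have passed, since its smallest p times the 240 families was 0.240. A run of 20000, made because of that, gave 0.048, just past the threshold, and the number was then raised to 100000 after that value had been seen.

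Reads shared between near-identical secretoglobin copies may add to that result. With the peaks whose 32-mers all occur once the fold over rotation was 0, since none of the 11 peaks on these genes qualified. That was the outcome set in advance for shared reads, but the peaks had 91.6% unique 32-mers, between 82.4% and 97.6% each, so the explanation and a mark on these genes cannot be told apart with these lists.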
